A study of Mus musculus with 10 samples.

How the data were processed

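The series measured the binding of Brd2, Brd4, Nipbl, Smc1 and Smc3 in primary mouse Th17 cells by ChIP-seq. Per the labels' protocols, naive CD4+ T cells from spleen were activated with antibodies to CD3 and CD28 in the presence of IL6 and TGFb. The protocols give a culture time of 48 to 72 h, and the design text gives 48 h. Whole-cell lysates were sonicated, fragments of 200 to 300 bp were selected, and libraries were amplified with 16 cycles of PCR, per the labels' protocols. The labels name antibodies from Bethyl for Brd2, Brd4, Nipbl and Smc1 and from Abcam for Smc3. Per the submitters' processing notes, CASAVA 1.4, Bowtie2 and MACS 1.4 were used with the mm9 build. The notes do not say which library served as the control of each list, and the caller's settings are not given in the sources used here.

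The 7 deposited files are lists of peaks called per library, with a chromosome, a start, an end, a name and a score. The score is the authors' deposited value for each peak, on the scale of MACS, minus 10 times the log10 of the p-value. In the deposited lists the lowest scores were 50.0 or just above, so weaker peaks had been left out before deposition. High scores collect at 3100, which 121 group 1 Brd4 peaks share exactly, so ranks among the strongest peaks of that list are partly ties. Scores depend on depth and control, and were used only to rank, describe or filter peaks within a list. A peak list gives no read counts: depth was unknown, no signal could be compared at a site, and a site missing from a list can still have been bound. Within each list no peaks overlapped each other. Files were assigned to samples by the record that ties each file to its sample, and groups were taken from the labels, since the names of the Smc1 and Smc3 files also mention Brd4.

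Each of the 10 samples formed its own group, so there was no test between conditions. Peaks counted as shared when they overlapped by at least 1 bp. Shares of peaks were given with 95% Wilson intervals and differences of shares with 95% Newcombe intervals. Both treat peaks as independent, and cover counting error only. Neighbouring peaks are not independent, so the intervals are too narrow by an unknown amount. The chance level was the mean over 1000 random placements of peaks of the same lengths on the same chromosome, between the first and the last peak position over all lists, without regard to mappability. Cohesin sites were the stretches covered by both an Smc1 and an Smc3 peak. Clustered regions joined neighbouring peaks at a distance fixed beforehand, with 12497 bp as the widest gap joined, and needed at least 3 peaks, and their overlaps were set against 200 random placements. Quartiles split each list by its own score. Start positions in the files were raised by 1 bp, so that positions are 1-based.

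The peaks named in the text followed a rule written before the data were examined. For each comparison it took the 8 highest-scoring peaks shared by both lists, ranked by the first list, and the 8 highest found in a single list, and, for the Brd2 and Brd4 lists, the 3 clustered regions with the most peaks. The text gives some of these and summarises the others. The rule also asked for gene names, fixed gene lists, positions relative to genes, and CTCF and STAT motifs. Those parts were not run, because the reference table available here is of another mouse build than mm9 and no mm9 genome or annotation was used. Sites are therefore named by position alone.

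The alternatives fixed beforehand were a required overlap of 50% of the shorter peak, a distance of up to 1 kb, a score of at least 100 in every list, the 2000 highest-scoring peaks of each list, chromosomes 1 to 19 and X only, any Smc1 or Smc3 peak as a cohesin site, peaks drawn from all lists as the background, and a joining distance of 5 kb. Several analyses were chosen after seeing the data. These were the 500 bp windows around peak centres, the exclusion of the 3 windows of 5 Mb with the most knockout peaks, the backgrounds drawn from the lists other than Smc1 and Smc3 and other than the knockout list, the comparison of knockout and other Brd4 peaks at equal width, the alternatives for the difference between Brd2 and Brd4, the look at the 100 highest wild-type peaks, the score quartiles of lists other than wild-type Brd4, the split of Smc1 peaks by Smc3, and the count of identical start positions.

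Overlaps, random placements and intervals were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9. The overlap code was tested on simulated lists of 2000 peaks with the widths of the Brd2 list, set on or off the Smc3 peaks, and in all 3 settings the planted share was recovered exactly. In 10000 simulated differences of shares, 9494 of the 95% intervals held the true value. Random placement was also checked against an exact count on a single chromosome.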

Results

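Brd2, Brd4 and cohesin were mapped by chromatin immunoprecipitation with sequencing (ChIP-seq) in mouse Th17 cells, the CD4+ helper T cells that make interleukin 17. The cells were grown from naive C57BL/6 spleen T cells with 20 ng/mL IL6 and 2.5 ng/mL TGFb. Brd2 and Brd4 are bromodomain proteins that bind acetylated histones. Smc1 and Smc3 are the long arms of the cohesin ring, and Nipbl loads that ring onto DNA. Stat3 is the transcription factor that IL6 activates and that drives the Th17 programme. The 10 libraries formed 10 groups of 1 sample each, so no comparison had replicates, and no p-value was computed. The labels placed the Brd2 and Brd4 libraries in group 1. Brd4 from wild-type cells, Brd4 from Stat3 knockout cells, Nipbl, Smc1 and Smc3 carried the label of group 2. For 7 libraries a list of called peaks was analysed, and the 3 input libraries had no peak list here.

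The Smc3 list was the longest, with 33776 peaks, ahead of Smc1 with 29857 and Nipbl with 19664. Brd2 had 14485 peaks with a median width of 929 bp, and Brd4 of group 1 had 8831 peaks of 1055 bp. The wild-type Brd4 list of group 2 held 4746 peaks of 558 bp. The Stat3 knockout Brd4 list held 1301 peaks with a median width of 213 bp. Covered length ran from 0.405 Mb in the knockout list to 23.9 Mb for Smc3. The lowest deposited score was about 50 in all 7 lists. Median scores were 126 for Smc3, 102 for Brd4 of group 1, 93.6 for Brd2, 88.5 for Smc1, 77.0 for Nipbl, 65.0 for wild-type Brd4 of group 2 and 64.2 for the knockout. Read depth was unknown for every library, so differences in the number of peaks were not compared between lists. Intervals below are 95% Wilson or Newcombe intervals, which cover counting error only and compare these libraries, not the conditions.

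The title of the series sets Brd2 against Brd4, and the first comparison asked how far their sites coincided in group 1. Of the Brd2 peaks, 30.4% overlapped a Brd4 peak (4408 of 14485; interval 29.7% to 31.2%). Of the Brd4 peaks, 50.2% overlapped a Brd2 peak (4436 of 8831; 49.2% to 51.3%). Peaks of the same lengths placed at random on the same chromosomes overlapped at 0.923% and 1.58%. Shared Brd2 peaks were wider than those without Brd4, at medians of 1595 and 675 bp, and had a higher median score, 138 against 84.2. The share of Brd4 peaks with Brd2 increased across quartiles of the Brd4 score, from 30.3% in the lowest to 78.4% in the highest. The Brd2 quartiles ran from 17.9% to 53.4% on Brd4 peaks. All positions are given in the mm9 build.

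Strong shared sites included chromosome 1 at 146151635 to 146159140, chromosome 15 at 9452202 to 9466357 and chromosome 19 at 11556668 to 11566828, each with a Brd2 score of 3100. Those 3 peaks overlapped peaks in 6 of the 7 lists, all but the knockout list. The highest Brd2 peak without Brd4 lay on chromosome 16 at 11423295 to 11424471, with a score of 2307, where Nipbl, Smc1 and Smc3 also had peaks. The next peaks, on chromosome 2 at 90756506 to 90759125 (score 1641) and on chromosome 14 at 51489368 to 51491406 (score 1529), overlapped no peak of another list. The 8 highest Brd4 peaks without Brd2 had scores of 2325 to 3100, and all 8 overlapped a wild-type Brd4 peak of group 2. Of these 8, 5 lay on chromosome 13 between 21923110 and 23856620, and each of the 5 overlapped Nipbl, Smc1 and Smc3 peaks. The widest, 19223 bp, lay on chromosome 3 at 101073582 to 101092804.

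Cohesin was mapped to ask where its proteins sit relative to both bromodomain proteins. Brd2 peaks lay on cohesin sites, defined as stretches covered by an Smc1 and an Smc3 peak, more often than Brd4 peaks. The shares were 40.0% for Brd2 (39.2% to 40.8%) and 16.2% for Brd4 of group 1 (15.5% to 17.0%), a difference of 23.8 percentage points (22.7 to 24.9). Wild-type Brd4 of group 2 was at 14.2% (13.2% to 15.2%). On Smc1 peaks alone the shares were 43.3% for Brd2 and 19.1% for Brd4, and on Smc3 peaks 54.3% and 29.6%. Nipbl peaks did not separate the proteins in this way, with 21.7% of Brd2 and 22.7% of Brd4 peaks on them, a difference of -1.02 points (-2.12 to 0.0799). With 500 bp windows around peak centres the Nipbl difference had the other sign, 1.01 points (0.00393 to 2.01).

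The difference was widest between the peaks that Brd2 and Brd4 did not share. Brd2 peaks without Brd4 overlapped cohesin sites at 46.9% (46.0% to 47.9%), shared Brd2 peaks at 24.3% (23.0% to 25.5%), and Brd4 peaks without Brd2 at 8.85% (8.05% to 9.73%). On Smc3 peaks the same classes had 60.0%, 41.1% and 18.7%. On Nipbl peaks the order changed, with 31.2% of the shared peaks, 17.6% of the Brd2 peaks without Brd4 and 14.9% of the Brd4 peaks without Brd2. The median distance to the nearest cohesin site was 2.53 kb for Brd2 peaks without Brd4, against 15.4 kb for Brd4 peaks without Brd2.

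**Figure D1:**
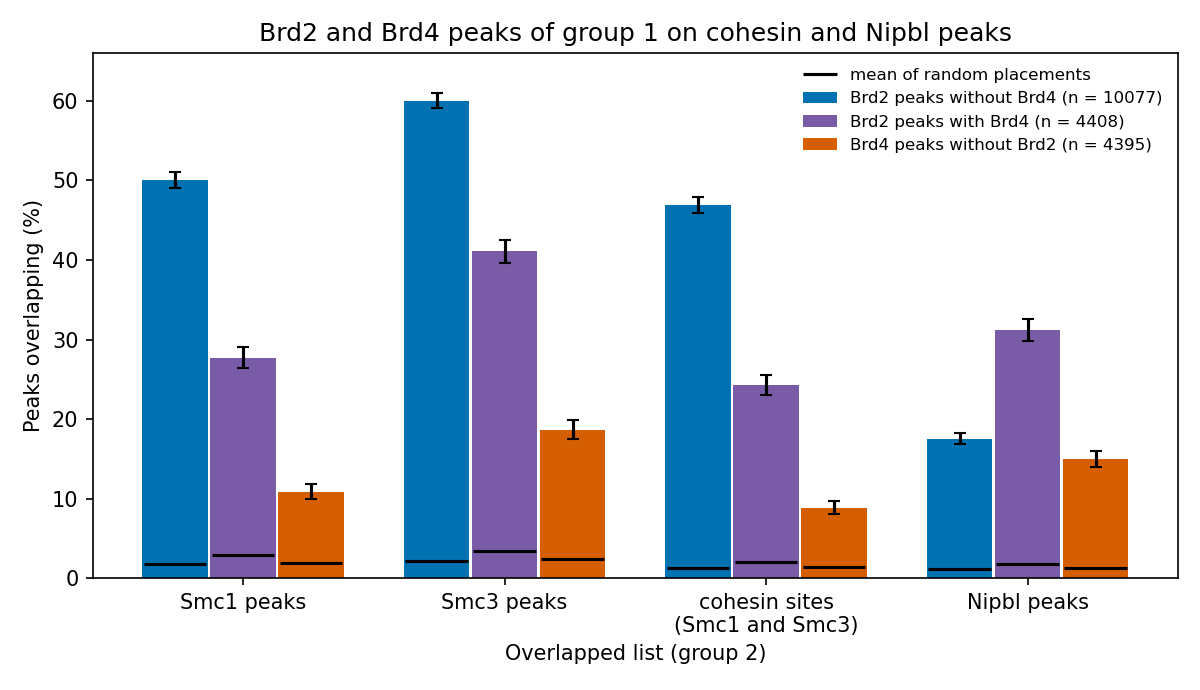
Share of peaks in percent (bars, vertical axis) that overlapped Smc1 peaks, Smc3 peaks, cohesin sites or Nipbl peaks (horizontal axis), for Brd2 peaks without Brd4, Brd2 peaks with Brd4 and Brd4 peaks without Brd2 in group 1; whiskers are 95% Wilson intervals and black lines the mean of 1000 random placements. On cohesin sites the bars fall from 46.9% to 24.3% and 8.85%, and on Nipbl peaks the shared class is highest at 31.2%.

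At full peak width, score changed this picture for Brd4 more than for Brd2. Across Brd4 score quartiles the share on cohesin sites went from 9.60% to 27.2%, while Brd2 quartiles lay between 36.4% and 45.0% without a steady order. Median width also grew from the lowest to the highest quartile, from 569 to 2446 bp for Brd4 and from 579 to 1704 bp for Brd2. In 500 bp windows around peak centres, Brd2 changed more, from 36.8% over all peaks to 26.3% among the 2000 highest. Brd4 went from 11.6% to 15.25% in such windows. Among the 2000 highest-scoring peaks at full width, 36.6% of Brd2 and 28.1% of Brd4 peaks lay on cohesin sites. That was a difference of 8.55 points (5.66 to 11.4). On Smc3 peaks that difference was 6.25 points (3.25 to 9.24) in 500 bp windows, and at full width 1.55 points (-1.55 to 4.64), an interval that includes 0. With the Smc1 and Smc3 lists also limited to their 2000 highest peaks, the shares were 6.35% and 3.25%, and the difference was 3.10 points (1.78 to 4.45). Random placement gave 1.49% of Brd2 and 1.73% of Brd4 peaks on cohesin sites, so the observed shares were 26.9 and 9.39 times those. Against peaks drawn from all 7 lists, which include Smc1 and Smc3, the ratios were 0.841 and 0.342. Against peaks drawn from the lists other than Smc1 and Smc3, a choice made after seeing the data, they were 1.57 for Brd2 and 0.635 for Brd4.

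Smc1 and Smc3, parts of the same complex, shared most of their sites. Of the Smc1 peaks, 69.4% overlapped an Smc3 peak (68.9% to 70.0%; random placement 1.75%), and 60.2% of the Smc3 peaks overlapped an Smc1 peak (59.7% to 60.8%; random 1.53%). These overlaps formed 20916 cohesin sites with a median width of 513 bp. In the highest quartile of score, 97.2% of Smc1 peaks had an Smc3 peak and 97.8% of Smc3 peaks had an Smc1 peak, against 40.7% and 26.4% in the lowest quartiles. Across the 20734 shared Smc1 peaks the deposited scores correlated at a Spearman rho of 0.67, a value across peaks, which are not independent replicates. The strongest shared Smc1 peak lay on chromosome 2 at 98502303 to 98503231, with a score of 3152 and peaks in 6 lists. A set of 3 others lay on chromosome 4 between 88418943 and 88452848, each with Brd2 and Nipbl peaks.

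A minority of Nipbl peaks overlapped cohesin sites, which need both Smc1 and Smc3. Of its 19664 peaks, 23.3% overlapped a cohesin site (22.8% to 23.9%; random 0.924%), and 47.9% overlapped neither an Smc1 nor an Smc3 peak (47.2% to 48.6%). Another 20.2% overlapped Smc1 alone and 8.48% Smc3 alone. The share on cohesin sites went from 11.7% in the lowest quartile of Nipbl score to 46.7% in the highest. Overlap was higher with Smc1, at 43.6% (42.9% to 44.3%), than with Smc3, at 31.9% (31.3% to 32.6%), although the Smc3 list was longer. Smc1 peaks without Smc3 overlapped Nipbl at 42.2% (41.2% to 43.3%), against 22.0% (21.5% to 22.6%) for Smc1 peaks with Smc3. By comparison, 5.67% of Smc1 peaks without Smc3 overlapped Brd2, against 29.2% of those with Smc3. The 8 highest Smc1 peaks without Smc3 all lay on chromosome 6 between 47602205 and 47714614, with scores of 743 to 1799, and all 8 overlapped Nipbl peaks and no other list. The highest Nipbl peak without Smc3 lay on chromosome 17 at 39979881 to 39985931 (score 3100) and overlapped Smc1 and Brd2 peaks. Mappability was not checked at this or any other named site, so peaks in several lists there need not mark joint binding.

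Brd4 was compared between wild-type and Stat3 knockout Th17 cells in group 2, the only contrast of genotypes. Few sites were found in both lists. Of the 4746 wild-type peaks, 109 (2.30%; 1.91% to 2.76%) overlapped a knockout peak, and of the 1301 knockout peaks, 135 (10.4%; 8.83% to 12.2%) overlapped a wild-type peak. Random placement gave 0.0449% and 0.184%. Against peaks drawn from all 7 lists, which include the knockout peaks themselves, the ratio for wild-type on knockout peaks was 1.32, and against peaks drawn from the lists other than the knockout list, a choice made after seeing the data, it was 3.87. The share of wild-type peaks on knockout peaks was 1.94% in the lowest score quartile and 3.79% (2.85% to 5.04%) in the highest. Of the 100 highest-scoring wild-type peaks, 5 overlapped a knockout peak, while all 100 overlapped a Brd4 peak of group 1. The lists overlapped were unlike in size, since the group 1 Brd4 list covered 14.2 Mb and the knockout list 0.405 Mb. The 2280 wild-type peaks that recurred in group 1 overlapped the knockout list at 2.24% (1.71% to 2.93%), and the 2466 that did not recur at 2.35% (1.82% to 3.03%). The Brd4 lists hold no measure of Stat3 itself, so the genotype label could not be checked, and with 1 library per genotype the difference had no replicate check.

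The highest wild-type Brd4 peaks without a knockout peak included chromosome 13 at 23646522 to 23648552 (score 1894), chromosome 3 at 96042131 to 96044605 (score 1815) and chromosome 9 at 107201934 to 107212686 (score 1471). All 8 of the highest such peaks overlapped cohesin sites, as did 6 of the 8 highest wild-type peaks with a knockout peak. By wild-type score, the highest peaks found in both genotypes also lay on chromosome 13. They were at 21870949 to 21872928 (wild-type score 1300), 23673202 to 23674933 (score 1265) and 23713024 to 23714878 (score 1066). On that chromosome between 21812943 and 23856620 the knockout list had 4 peaks, with knockout scores of up to 69.8. Of the 8 highest knockout peaks without a wild-type peak, 4 lay on chromosome 5 between 15008014 and 15187674, with scores of 287 to 339, and overlapped no other list. The highest, on chromosome X at 166443316 to 166446980 (score 505), also overlapped a Nipbl peak.

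The knockout peaks were unevenly spread along the genome. Windows of 5 Mb on chromosome X from 120 to 125 Mb, on chromosome 5 from 15 to 20 Mb and on chromosome 5 from 10 to 15 Mb held 217, 136 and 84 of the knockout peaks, together 33.6%. The same 3 windows held 0.759% of the wild-type Brd4 peaks. The chromosome X window also held 203 Brd2, 171 group 1 Brd4 and 234 Nipbl peaks, but 32 wild-type Brd4 peaks of group 2. Chromosome X carried 21.4% of the knockout peaks and 2.59% of the wild-type peaks. In all, 70.8% of the knockout peaks (68.3% to 73.2%) overlapped no peak of the other 6 lists, against 42.2% for wild-type Brd4, 34.2% for group 1 Brd4 and 20.4% for Brd2. Without the 3 windows, a choice made after seeing the data, 13.7% (11.5% to 16.1%) of the knockout peaks overlapped wild-type peaks.

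**Figure D2:**
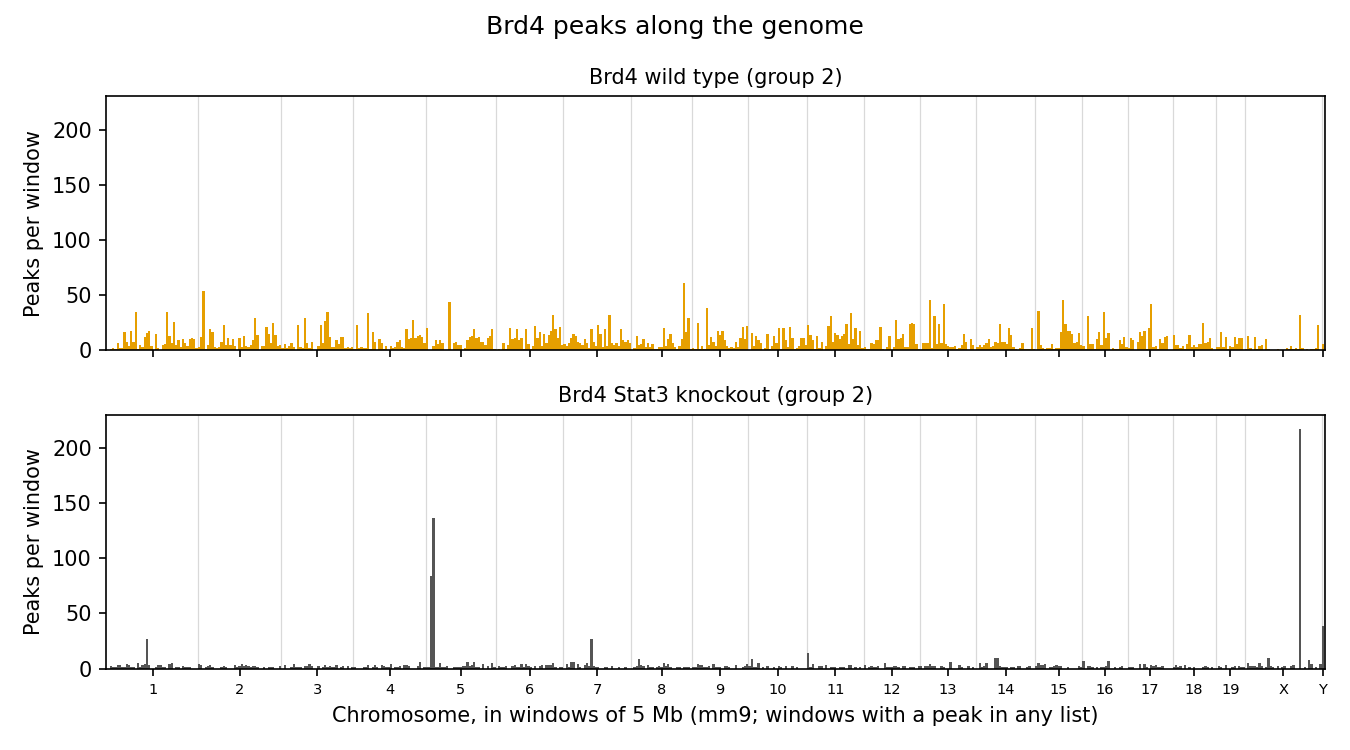
Number of Brd4 peaks (vertical axis) per 5 Mb window along the mm9 chromosomes (horizontal axis) in wild-type (upper panel) and Stat3 knockout (lower panel) cells of group 2, 1 library each. The tallest knockout bars hold 217 peaks on chromosome X and 136 and 84 on chromosome 5, while no wild-type bar exceeds 61.

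Wild-type Brd4 was mapped in both groups, which gave the only repeat of an antibody in cells of the same genotype. Of the wild-type peaks of group 2, 48.0% (46.6% to 49.5%) overlapped a group 1 peak, against 0.830% at random, and 19.4% (18.6% to 20.2%) of the group 1 peaks overlapped a group 2 peak. The share increased with the group 2 score, from 24.0% and 26.3% in the lower quartiles to 53.5% and 88.4% in the upper quartiles. With a score of at least 100 required in every list, the share was 83.7%. Over the 2280 overlapping peaks the scores correlated at a Spearman rho of 0.39, again across peaks. The group 2 peaks that recurred had a median width of 944 bp and 70.1% of them overlapped Brd2, against 426 bp and 6.37% for those that did not.

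The strongest group 1 Brd4 peaks absent from the group 2 wild-type list lay on chromosome 7 at 85875299 to 85883170 (score 3190), chromosome 1 at 20728048 to 20732340 (score 3100) and chromosome 1 at 146161312 to 146167554 (score 3100). All 8 of the highest such peaks overlapped Brd2 peaks of group 1. The strongest group 2 peak absent from group 1 was on chromosome 17 at 32366076 to 32366632 (score 428).

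**Figure D3:**
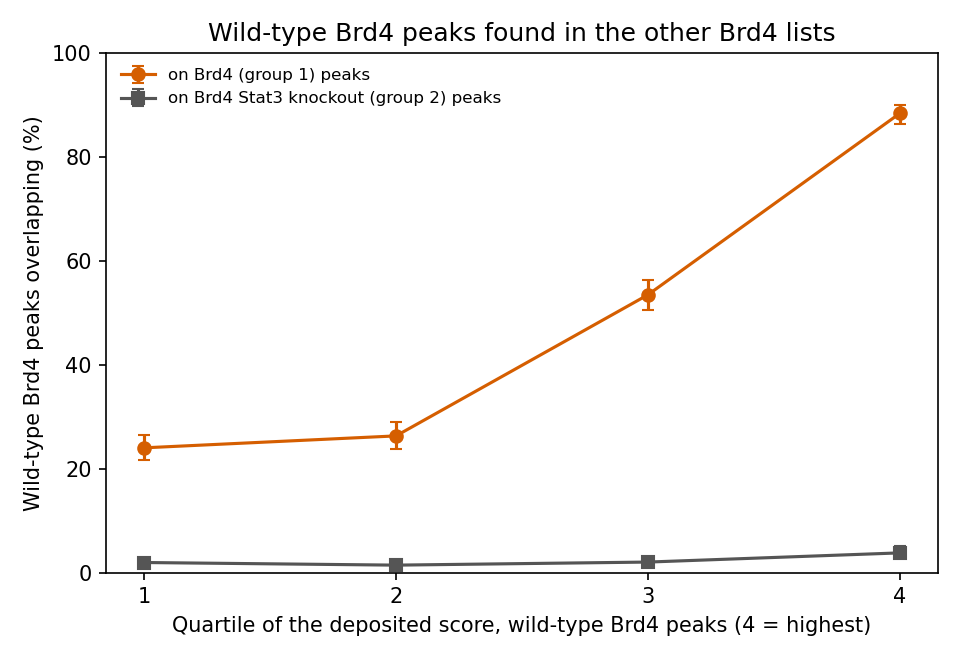
Share of wild-type Brd4 peaks of group 2 in percent (vertical axis) that overlapped a group 1 Brd4 peak (circles) or a Stat3 knockout Brd4 peak (squares), by quartile of the wild-type score (horizontal axis, 4 the highest); whiskers are 95% Wilson intervals. The share on group 1 peaks goes from 24.0% to 88.4%, and the share on knockout peaks from 1.94% to 3.79%. The lists overlapped differ in length, with 8831 group 1 and 1301 knockout peaks.

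In the lists as called, Brd4 peaks of group 1 were more clustered than Brd2 peaks. Some neighbouring group 1 Brd4 peaks nearly touched, as at 32433369 and 32433379 on chromosome 4. Counts of clustered peaks therefore depend on where peaks were split in calling. The share of peaks in regions was not set against random placement. When neighbouring peaks were joined into regions, across gaps of up to 12497 bp, 935 regions with at least 3 Brd4 peaks held 56.6% of the group 1 Brd4 peaks (55.6% to 57.7%), while 748 Brd2 regions held 22.5% of the Brd2 peaks (21.9% to 23.2%). The wild-type Brd4 list of group 2 had 295 such regions with 31.5% of its peaks, and 77.6% of them overlapped a group 1 Brd4 region. With a score of at least 100 the numbers of regions were 493 for group 1 Brd4, 248 for Brd2 and 115 for wild-type Brd4. The Brd4 region with the most peaks, 40 over 189 kb, lay on chromosome 4 at 32325984 to 32514747 and also held 22 Brd2, 30 wild-type Brd4 and 21 Smc3 peaks but no knockout peak. The next regions, on chromosome 2 at 11061200 to 11217713 (36 Brd4 peaks) and chromosome 15 at 62553884 to 62671499 (34), likewise held no knockout peak. In the wild-type list of group 2 the region with the most peaks, 22, lay within the same chromosome 2 region, at 11063466 to 11141128. Brd2 had its fullest region on chromosome X at 120725850 to 120790915, with 26 Brd2, 18 group 1 Brd4 and 14 knockout peaks but no wild-type Brd4 peak of group 2. It lay in the chromosome X window from 120 to 125 Mb, the fullest 5 Mb window of the Brd2, group 1 Brd4, Nipbl and knockout lists. Mappability was not checked there. The knockout list had 54 regions, and its 3 fullest, with 90, 86 and 34 peaks, lay on chromosome 5 between 14900107 and 15221586.

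**Figure D4:**
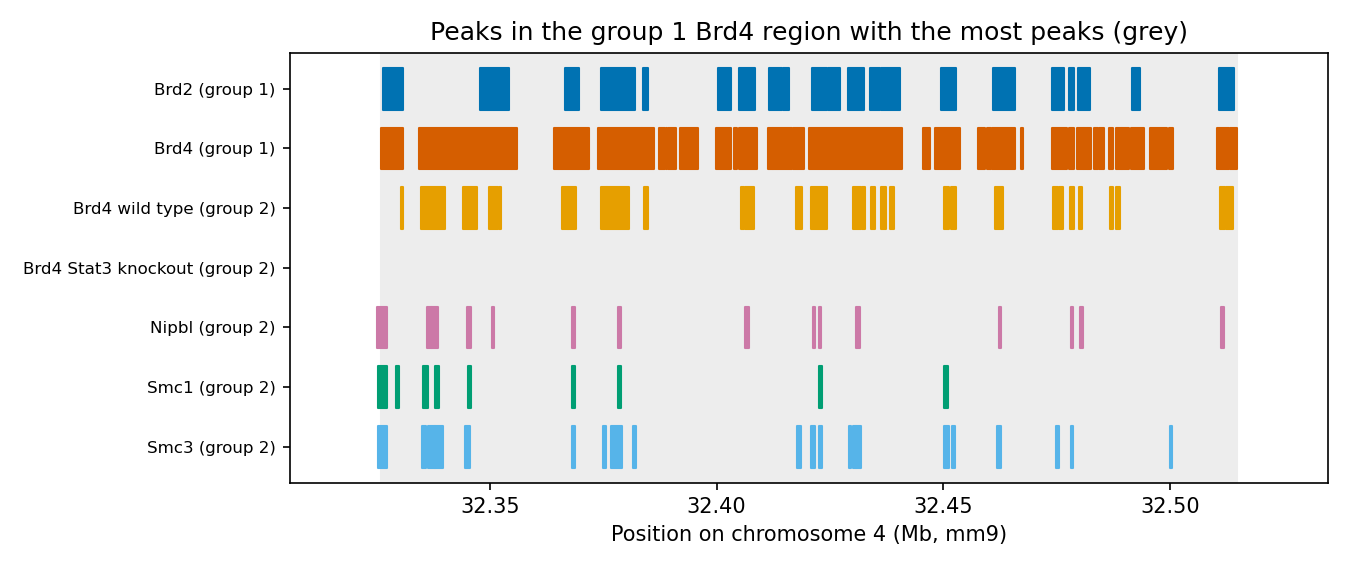
Map of the group 1 Brd4 region with the most peaks, on chromosome 4 from 32325984 to 32514747 (grey; horizontal axis in Mb, mm9), with each peak of the 7 lists drawn to scale as a box in its row. The region holds 40 group 1 Brd4, 22 Brd2, 30 wild-type Brd4, 15 Nipbl, 10 Smc1 and 21 Smc3 peaks, and the Stat3 knockout row is empty.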

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

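The settings for the difference between Brd2 and Brd4, the 500 bp windows, the exclusion of dense windows and the backgrounds without Smc1 and Smc3 or without the knockout list were chosen after seeing the data; the others were set before the data were examined. Under other settings, 31 values stayed within the interval of the reported value or within 1.5 times the reported count, 56 lay outside it, and 3 changed direction. Brd2 exceeded Brd4 on cohesin sites in all 7 other settings. The causes of the changes were not tested, except for the backgrounds drawn from peaks.

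Counting peaks within 1 kb as shared gave 32.5% of Brd2 on Brd4, 58.1% of Brd4 on Brd2, 42.5% of Brd2 and 21.0% of Brd4 on cohesin sites (difference 21.5 points), 24.8% of Brd2 and 28.4% of Brd4 on Nipbl, 27.4% of Nipbl on cohesin sites, 71.9% of Smc1 on Smc3, 63.5% of Smc3 on Smc1, 2.78% of wild-type Brd4 on knockout, 12.8% of knockout on wild type, and 50.2% of wild-type Brd4 on group 1 Brd4. Requiring 50% of the shorter peak gave 48.0% of Brd4 on Brd2 and 20.7% of Brd2 on Nipbl.

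A score of at least 100 in every list gave 32.2% of Brd2 on Brd4, 48.1% of Brd4 on Brd2, 27.6% of Brd2 and 12.4% of Brd4 on cohesin sites (difference 15.2 points), 14.4% of Brd2 and 15.4% of Brd4 on Nipbl, 24.4% of Nipbl on cohesin sites, 84.1% of Smc1 on Smc3, 52.9% of Smc3 on Smc1, 1.36% of wild-type Brd4 on knockout (117 times random placement), and 83.7% of wild-type Brd4 on group 1. It left 248 Brd2, 493 group 1 Brd4, 115 wild-type Brd4 and 12 knockout clustered regions. Joining peaks within 5 kb gave 463 Brd2 regions.

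The 2000 highest-scoring peaks per list, which shortened every list but the knockout list of 1301, gave 37.3% of Brd2 on Brd4, 37.4% of Brd4 on Brd2, 6.35% of Brd2 and 3.25% of Brd4 on cohesin sites (difference 3.10 points), 9.95% of Brd2 and 10.75% of Brd4 on Nipbl, 10% of Nipbl on cohesin sites, 68.4% of Smc1 on Smc3, 68.05% of Smc3 on Smc1, 3.15% of wild-type Brd4 on knockout, 6.46% of knockout on wild type, and 57.2% of wild-type Brd4 on group 1.

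With any Smc1 or Smc3 peak as a cohesin site, the shares were 57.3% for Brd2 and 32.2% for Brd4 (difference 25.1 points). With 500 bp windows around peak centres they were 36.8% and 11.6% (difference 25.2 points). Without the 3 densest windows 13.7% of knockout peaks lay on wild-type peaks. Drawn from the peaks of all lists, a pool that includes the Smc1 and Smc3 peaks that make up the sites, the background turned the ratio on cohesin sites to 0.841 for Brd2 and 0.342 for Brd4. Wild-type Brd4 on knockout was at 1.32 against a pool that includes the knockout peaks, each of which overlaps itself, and at 3.87 without them. Drawn from the lists other than Smc1 and Smc3, the background gave 1.57 for Brd2 and 0.635 for Brd4, which restates the shares of the lists: most of that pool is Brd2 and Nipbl, at 40.0% and 23.3% on cohesin sites, against 16.2% of group 1 Brd4, 14.2% of wild-type Brd4 and 3.23% of knockout Brd4.

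Limiting the lists to chromosomes 1 to 19 and X moved none of 13 values beyond its interval. Settings on genes, transcription starts and motifs had also been set but were not run for lack of an mm9 annotation and genome. No replicate could be left out, and no paired analysis was possible because each group had 1 sample. Depth is unknown for all 7 lists, so a peak missing from a list, above all from the knockout list, cannot be read as lost binding.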

Other observations

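In 3 places, chosen after their values were seen, sites crowded together in lists of several proteins. On chromosome 13 between 21812943 and 23856620 lay 5 of the 8 highest group 1 Brd4 peaks without Brd2, with scores of up to 3060. The highest wild-type Brd4 peak of group 2, with a score of 1894, lay there too. Of the 8 Brd4 peaks found in both genotypes with the highest wild-type scores, 4 lay there as well. Knockout scores in that stretch reached 69.8. On chromosome 6 between 47602205 and 47723314, Nipbl and Smc1 had peaks of up to 2413 and 1799, and Smc3 overlapped the Nipbl peaks at 47717134 to 47718931 and 47721716 to 47723314. On chromosome 2 at 98502303 to 98507582, Smc1 peaks with scores of 3152 and 3100 coincided with peaks of Brd2, Brd4, Nipbl and Smc3. The knockout Brd4 list also had 1 peak in that stretch, with a score of 87.85, so every list had a peak there. Mappability was not checked, and these peaks need not mark joint binding.

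When the 7 lists were merged, 50.8% of the regions held a peak of a single list, and 12 regions held a peak of all 7. Among them, also picked after their values were seen, were chromosome 6 at 41486884 to 41507065 and chromosome 13 at 23672988 to 23679217.

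For the patterns below, the peak-width, weak-Brd2-peak and low-enrichment tests were chosen after seeing the data, and the tests of dense windows, of lost binding without Stat3, of sites where any antibody gives a peak, and of reads common to Nipbl and Smc1 were chosen only after their results were seen. The knockout Brd4 list overlapped few wild-type peaks. Its dense windows did not lower its share on group 1 Brd4 peaks. At full width that share was 17.2% (13.9% to 21.0%) inside them and 13.4% (11.3% to 15.9%) outside. In 500 bp windows, 13.5% (11.4% to 16.0%) of the peaks outside them lay on group 1 Brd4 peaks, against 48.0% of wild-type peaks. For the share on wild-type peaks the dense windows cannot be told apart from other causes. Outside them it was 13.8% (11.6% to 16.2%), against 16.3% (15.5% to 17.1%) of group 1 Brd4 peaks, and the intervals overlap. With a score of at least 100, it was 33.3% (23.7% to 44.6%) of 75 knockout peaks outside the dense windows. Of group 1 Brd4 peaks with such scores it was 26.0% (24.7% to 27.3%), and these intervals also overlap. The group 1 list of 8831 peaks is longer than the wild-type list of 4746, which limits the share it can reach. Similar shares therefore do not show that knockout peaks match wild-type peaks as well as group 1 peaks do. On group 1 Brd4 peaks the shares at that score were 38.7% of these knockout peaks and 89.6% of wild-type peaks. Low enrichment or depth of the knockout library is a candidate explanation: outside the dense windows 71.6% of its peaks (68.5% to 74.5%) overlapped no other list. Loss of Brd4 without Stat3 stays open, since 5 of the 100 highest wild-type peaks overlapped a knockout peak, which both explanations allow, and with 1 library per genotype these cannot be told apart.

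Brd2 peaks lay on cohesin sites more often than Brd4 peaks. Peak width did not account for this, as 500 bp windows gave a difference of 25.2 points (24.2 to 26.2). Weak Brd2 peaks were not the sole source, since the 2000 highest peaks of each in such windows differed by 11.05 points (8.55 to 13.5). On Smc3 peaks their difference was 6.25 points (3.25 to 9.24) in such windows, although at full width it was 1.55 points, with an interval that held 0. Sites where any antibody gives a peak were not the whole cause either, since the difference on Nipbl peaks was -1.02 points (-2.12 to 0.0799), or 1.01 points in 500 bp windows. The source of the difference stays open, since antibody quality and depth, each from 1 library, were not tested.

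Nipbl peaks overlapped Smc1 peaks more often than Smc3 peaks. The excess did not rest on weak peaks alone. Among the 2000 highest peaks of each list 17.9% of Nipbl peaks lay on Smc1 and 10.75% on Smc3, a difference of 7.15 points. That cut removed most of the overlap, so it cannot say how much of the full excess came from weak Smc1 peaks. In the full lists 3973 Nipbl peaks lay on Smc1 alone and 1667 on Smc3 alone. Smc1 peaks without Smc3 had a median score of 64.0, against 112 for those with Smc3. Reads or background common to the Nipbl and Smc1 libraries may contribute: their peaks shared 126 exact starts, 3.47 times (2.76 to 4.34) the mean number of starts 1 to 3 bp apart, against 1.15 times for Smc1 and Smc3 and 1.05 times for Nipbl and Smc3. Of these 126 starts, 97 were in Smc1 peaks without Smc3, out of 3854 such peaks on Nipbl, so identical starts covered a small part of the overlap. An excess may not be particular to this pair: group 1 Brd4 and Smc3 were at 2.84 times (1.13 to 6.59), on 9 exact starts. The intervals were not corrected for the number of pairs compared, so a ratio on so few starts is weak evidence. Every other ratio that could be computed had an interval that held 1. No biological explanation was tested.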
